A study of Homo sapiens with 8 samples.

How the data were processed

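RNA of T47D cells was measured on Affymetrix Human Gene 1.0 ST arrays, the platform named in the probe table. Per the labels, the cells carried either a conditional EglN2 shRNA or the Scr control shRNA, total RNA was labelled with biotin, and doxycycline was used at 1 ug/ml for 0 or 48 h. Groups and replicate numbers were taken from the sample titles: 4 groups (Scr day 0, Scr day 2, EglN2 shRNA day 0, EglN2 shRNA day 2) with 2 arrays each.

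The deposited values are log2 levels per probe set, made with RMA in Affymetrix Expression Console, per the submitters' processing notes. Versions are not given in the sources used here. RMA corrects background, normalizes between arrays and summarises the probes of a set, which compresses differences of dim genes. The values carry 2 decimals and run from 2.73 to 15.25, and the array medians over the whole table lie between 7.17 and 7.26. They were used as deposited, with no further scaling. Scanner files, and so the signal over background of each probe, were not analysed here.

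The table holds 33297 probe sets. The platform's gene table named 1 gene for 19460 of them, several for 1754 and none for 12083. Single names were updated by gene ID through the RefSeq gene table of assembly GRCh38.p14, which matched 19429 and left 31 under the name in the platform's table. No genome build is named for the array, so no coordinates are given. The 21214 probe sets with a gene name were tested. The unnamed ones were left out of the main tests, since 4203 of them have IDs below the first named one and may be control sets, which the files do not say. The planned report of Affymetrix control sets (3' against 5' signal, spike-ins) was not made, because no probe set carries a control name.

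Group means were fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that each probe set had 1 estimate of its spread, with 4 residual degrees of freedom plus 5.53 from the prior (prior SD 0.124). The 5 comparisons were the day 2 minus day 0 change in each line, the difference of those changes, and the difference between the lines at each day. Tests were two-sided, adjusted by Benjamini-Hochberg over 21214 probe sets, with a threshold of 0.05. If nothing changed, 5% of probe sets would on average have an unadjusted p under 0.05. An exact permutation test of 2 arrays against 2 cannot go below p = 0.333, so none was run. Gene lists were tested with camera at a preset correlation between genes of 0.01, on the probe set with the highest mean for each of 18417 genes, and again with an estimated correlation; no list was called with the latter in any of the 5 comparisons. The estimated form also raised p for some lists whose estimated correlation was below 0.01. An example is the cyclin list in the EglN2 shRNA line (estimated correlation -0.0381, camera p = 0.0229 preset and 0.0652 estimated). In the estimated form camera also takes its p from the 4 residual degrees of freedom, whatever the correlation. A lost call therefore need not come from correlation between genes. A list needed 5 measured members. The 34 lists (833 genes) were written from general knowledge of the genes. Some genes are in several lists, so calls of different lists are not independent. STC2 and DDIT4 are in the amino acid stress and hypoxia (HIF target) lists, and PDK1 and ALDOC in the hypoxia and glycolysis lists.

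Groups, comparisons, tests, gene lists, alternatives and the rule for the genes named were fixed before the data were examined, except where a choice is said to have been made later. The rule named EGLN2, CCND1, EGLN1, EGLN3, HIF1A, EPAS1, ESR1 and PGR in every comparison. It added the 10 largest rises and 10 largest falls among single-gene probe sets past the threshold whose groups do not overlap, or, where none passed in a direction, the 5 with the largest moderated t, given as values that did not pass. For the difference of changes, no overlap means that all 4 possible changes of one line lie on one side of those of the other. The groups of 2 did not overlap for 30.7% of probe sets in the EglN2 shRNA line's change, 47.8% in the Scr line's change, 45.0% between the lines at day 0 and 30.4% at day 2, where chance gives 33.3%. Of each list described, up to 4 members with the smallest p were named.

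The scripts were tested on simulated data with 200 of 21214 probe sets changed, 10 times. In the EglN2 shRNA line's change, 57.8% of those changed by 0.7 (log2) were recovered, 91.4% of those changed by 1 and 99.8% of those changed by 2, with 93 false calls among 1835. In the difference of changes, 12.4% were recovered at 0.7, 56.2% at 1 and 98.0% at 2. At day 2 between the lines, 93.4% were recovered at 1. These shares depend on the 200 planted changes, since the Benjamini-Hochberg adjustment is milder where many probe sets change. The real comparisons called 0 to 16 probe sets. The shares therefore do not say how often a real change of the same size would have been found. A list of genes shifted by 0.3 was called in 10 of 10 simulations, and 1 of 330 other lists was called. The simulated genes varied independently of each other. The 1 call in 330 therefore does not show how often lists of genes that move together are called.

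Alternatives tried were a replicate block, quantile normalization, median centring, leaving out the dimmest 30% of probe sets, an intensity trend and a robust prior in eBayes, 1 value per gene, array weights, a threshold of 0.1, only the 4 arrays compared, the mean of a gene's probe sets for lists, and leaving out each of the 8 arrays in turn. A fit of all probe sets of the table and the correlations within same-numbered replicates were also run, but were not among the alternatives fixed beforehand. Figures were drawn with matplotlib 3.10.9.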

Results

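Gene expression was measured in T47D cells, an established line of estrogen receptor positive human breast carcinoma. The cells had been infected with lentivirus carrying either a conditional hairpin RNA (shRNA) against EglN2 or a control hairpin named Scr, and both hairpins were used with doxycycline. RNA was taken at day 0, without doxycycline, and at day 2, after 48 h of doxycycline. Each of the 4 combinations of line and day was measured on 2 arrays, 8 in all. EGLN2 encodes a prolyl hydroxylase of the oxygen-sensing family, whose best known substrates are the alpha subunits of hypoxia-inducible factor (HIF). Values are RMA log2 levels per probe set, and 21214 probe sets with a gene name were tested. Over these probe sets the replicate arrays of a group correlated at 0.992 to 0.996, and the array medians lay between 7.81 and 7.86. With 2 arrays per group the number of arrays limits the precision: the median standard error of a difference between groups was 0.12 on the log2 scale. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

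EGLN2, the target of the hairpin, was lowest on the pair of arrays from the EglN2 shRNA line at day 2. Its probe set (8028940) read 8.26 and 8.29 there, against 8.85 and 9.04 in the same line at day 0. In the Scr line it read 8.97 and 9.0 at day 0 and 8.81 and 8.90 at day 2. This probe set also carries the name of the RAB4B-EGLN2 read-through transcript, so the 2 transcripts cannot be separated. The change in the EglN2 shRNA line was -0.67 (SE 0.11, 95% confidence interval -0.91 to -0.43), a level 62.9% of that at day 0. It did not pass the test over all probe sets (limma, adjusted p = 0.134).

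**Figure D1:**
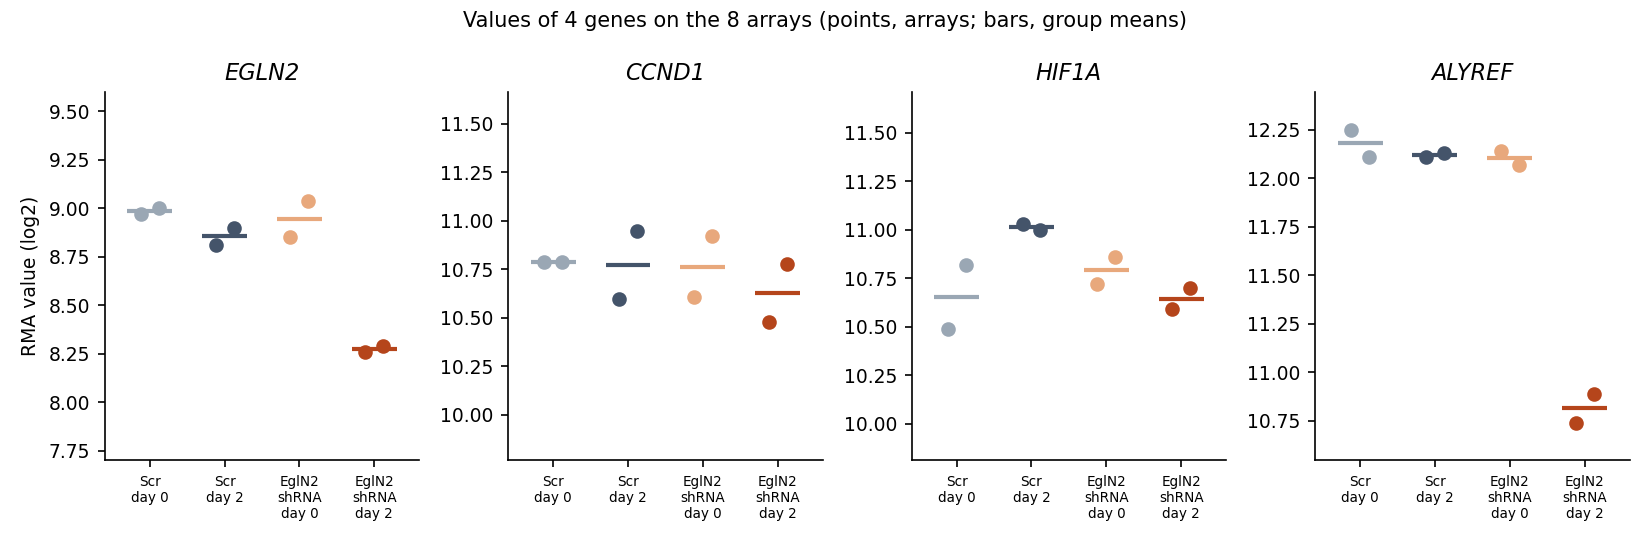
RMA values (log2, vertical axes of equal length) of EGLN2, CCND1, HIF1A and ALYREF on the 8 arrays, with 2 points per group for the replicates and a bar at the group mean. EGLN2 and ALYREF lie lowest on both arrays of the EglN2 shRNA line at day 2, at 8.26 and 8.29 and at 10.74 and 10.89, while CCND1 overlaps between groups.

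The first comparison asked what 48 h of doxycycline did in the cells carrying the EglN2 hairpin. ALYREF, which encodes an adaptor for the export of mRNA from the nucleus, fell from a mean of 12.11 to 10.81 (SD 0.05 and 0.11, n = 2 each). The log2 change was -1.29 (SE 0.11, adjusted p = 0.00506), or 2.45-fold, and a second ALYREF probe set fell by 1.26 (SE 0.11). It was the only gene past the threshold: 2 probe sets fell and 0 rose with limma. An unadjusted p under 0.05 was seen for 1224 probe sets (5.77%), near the share expected if nothing changed. Genes of the amino acid stress response, which are switched on by the transcription factor ATF4, were called higher as a list, with a median log2 change of 0.34 over 35 measured members (adjusted p = 0.110 with an estimated correlation). Chaperones of the heat shock response were called lower, with a median of -0.20 over 17 measured members (adjusted p = 0.554 with an estimated correlation).

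The amino acid stress list holds the enzymes and transporters of serine, asparagine and folate metabolism together with tRNA synthetases. Of its 35 measured members 32 had a positive change, and camera called the list higher (adjusted p = 7.65e-23; adjusted p = 0.110 with an estimated correlation). No member passed over all probe sets, but adjusted over the list alone 21 members rose and 1 fell. The folate enzyme ALDH1L2 changed by 0.94 (SE 0.14), the stress protein NUPR1 by 0.68 (SE 0.12), the secreted glycoprotein STC2 by 0.68 (SE 0.12) and the mitochondrial PEP carboxykinase PCK2 by 0.57 (SE 0.10), all past the threshold over the list alone. In the heat shock list 16 of 17 measured members had a negative change (adjusted p = 5.84e-09; adjusted p = 0.554 with an estimated correlation). Adjusted over the list alone, 5 members fell and 0 rose, among them HSPH1 at -0.90 (SE 0.21), CHORDC1 at -0.67 (SE 0.17), DNAJA1 at -0.42 (SE 0.12) and HSPA4L at -0.38 (SE 0.11).

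HIF target genes were called higher as a list, with a median change of 0.15 over 34 measured members, 25 of them positive (adjusted p = 3.75e-05; adjusted p = 0.599 with an estimated correlation). With adjustment over the list alone 2 members rose and 1 fell: STC2 and the glycolytic enzyme ALDOC, at 0.75 (SE 0.16), rose, and hexokinase HK2, at -0.48 (SE 0.11), fell. The HIF list median was 0.09 without day 2 replicate 1 of this line and 0.26 without day 2 replicate 2. The list of oxygen sensors themselves, with EGLN1, EGLN3 and HIF1A, was not called (adjusted p = 0.793), with a median of -0.0025 but a mean of 0.01 and a test direction that was positive. The G1/S and replication list was called lower (median -0.10, 32 of 38 measured members negative, adjusted p = 3.75e-05; adjusted p = 0.723 with an estimated correlation). Its members with the smallest p were RRM2 at -0.46 (SE 0.12), the licensing factor CDT1 at -0.51 (SE 0.13) and CLSPN at -0.69 (SE 0.19), with 0 past the threshold adjusted over the list alone. Without the day 0 replicate 2 array of this line the replication call was lost (adjusted p = 0.235), and likewise without its day 2 replicate 1 array (adjusted p = 0.226).

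The antioxidant targets of NRF2 were called lower (median -0.08, 15 of 20 measured members negative, adjusted p = 0.0129; adjusted p = 0.723 with an estimated correlation). Adjusted over the list alone 3 members fell and 0 rose, among them the quinone reductase NQO1 at -0.56 (SE 0.10) and the glutathione synthesis subunit GCLM at -0.74 (SE 0.14). The TGF-beta response list was called lower (median -0.03, adjusted p = 0.0294; adjusted p = 0.554 with an estimated correlation), and adjusted over the list alone TIMP1 at -0.55 (SE 0.10), ID1 at -0.59 (SE 0.11) and ID3 at -0.58 (SE 0.12) fell. MYC and nucleolar targets (median -0.07), the proteasome (median -0.10) and mitosis genes (median -0.11) were called lower and fatty acid synthesis (median 0.11) higher. Their adjusted p were 0.00175, 0.000614, 0.0167 and 0.0396, and 0.599, 0.723, 0.723 and 0.757 as adjusted p with an estimated correlation, and 0 members of the 4 lists passed adjusted over the list alone. Each of these 6 calls was lost without at least 1 array of this line. Without day 0 replicate 1 the adjusted p was 0.0842 for MYC targets, 0.0549 for the proteasome, 0.292 for the TGF-beta list and 0.752 for fatty acid synthesis. Without day 2 replicate 2 it was 0.109 for NRF2 targets, 0.233 for the TGF-beta list and 0.928 for fatty acid synthesis. The mitosis call was lost without day 0 replicate 2 (adjusted p = 0.106) and turned direction without day 2 replicate 1 (adjusted p = 0.424).

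CCND1, which encodes cyclin D1, changed by -0.14 (SE 0.16, confidence interval -0.49 to 0.22, adjusted p = 0.980). The related hydroxylases EGLN1 (0.16, SE 0.11) and EGLN3 (-0.07, SE 0.13) did not pass, nor did HIF1A (-0.14, SE 0.13) or EPAS1 (0.02, SE 0.15). The estrogen receptor gene ESR1 has 2 probe sets, at 0.04 (SE 0.10) and -0.27 (SE 0.11), and the progesterone receptor gene PGR read -0.03 (SE 0.15), all short of the threshold. The positive changes with the largest moderated t that did not pass were those of the integrin subunit ITGA5 (0.83, adjusted p = 0.114), TYRP1 (0.72), ARHGAP15 (0.81), the glycogen phosphorylase PYGL (0.88) and the amino acid transporter SLC43A1 (0.69), the last 4 at an adjusted p of 0.134. The estrogen response list was not called (34 measured members, median -0.02, adjusted p = 0.398), nor were luminal epithelial markers (adjusted p = 0.348), p53 targets (adjusted p = 0.496), oxidative phosphorylation (adjusted p = 0.278) or markers of leukocytes and endothelium (adjusted p = 0.869). The ALYREF call ended, with 0 probe sets called, without day 0 replicate 1 or day 2 replicate 1 of this line, when only its 4 arrays were used, and when all 33297 probe sets of the table entered the fit. Without day 0 replicate 2, 1 probe set was called, and it was not one of the ALYREF pair.

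The second comparison asked what the same 48 h of doxycycline did in the Scr line. The amino acid stress list was called higher here too, with a median change of 0.34 over its 35 measured members (adjusted p = 4.36e-13; adjusted p = 0.302 with an estimated correlation). Lists of dividing cells were called higher: mitosis genes (median 0.24), replication-dependent histones (median 0.25) and centrosome and cilium genes (median 0.30), each with an adjusted p = 0.434 with an estimated correlation. No single gene passed in the main fit: limma called 0 of 21214 probe sets, 2726 (12.85%) had an unadjusted p under 0.05, and the smallest adjusted p was 0.0870. With a replicate block, an alternative not used in the main fit, 42 probe sets were called, 31 higher and 11 lower. EGLN2 read -0.13 (SE 0.11, confidence interval -0.37 to 0.11, adjusted p = 0.602).

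In the amino acid stress list 30 of 35 measured members had a positive change, and adjusted over the list alone 22 rose and 1 fell. The serine synthesis enzymes PSPH at 0.73 (SE 0.11), PHGDH at 0.60 (SE 0.11) and PSAT1 at 0.74 (SE 0.15) were among those that rose over the list alone, as was PCK2 at 0.56 (SE 0.10). Mitosis genes were positive in 33 of 35 measured members (adjusted p = 1.89e-09; adjusted p = 0.434 with an estimated correlation), with 0 past the threshold adjusted over the list alone, and values of 0.41 (SE 0.10) for NUSAP1 and 0.43 (SE 0.13) for CENPE. Histones were positive in 27 of 28 (adjusted p = 2.52e-07; adjusted p = 0.434 with an estimated correlation), with H2BC8 at 0.60 (SE 0.14). Centrosome and cilium genes were positive in 20 of 20 (adjusted p = 1.22e-06; adjusted p = 0.434 with an estimated correlation), and adjusted over the list alone the ciliary transport gene IFT88 rose, by 0.59 (SE 0.13). Without day 0 replicate 1 of the Scr line the histone median was 0.15 and the centrosome median 0.19, and without day 0 replicate 2 the histone median was 0.43.

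HIF targets were called higher in the Scr line (median 0.13, 26 of 34 measured members positive, adjusted p = 0.000297; adjusted p = 0.434 with an estimated correlation). Adjusted over the list alone 8 of them rose and 0 fell, including the collagen hydroxylase P4HA2 at 0.63 (SE 0.10), the kinase PDK1 at 0.69 (SE 0.14), STC2 at 0.53 (SE 0.12) and DDIT4 at 0.42 (SE 0.11). Interferon response genes were called higher (median 0.17, 33 measured members, adjusted p = 0.000910; adjusted p = 0.434 with an estimated correlation). Adjusted over the list alone 5 of them rose and 1 fell, with MX1 at 0.65 (SE 0.17) and PSMB8 at 0.57 (SE 0.14) among the rises and IFITM3 at -0.53 (SE 0.14) the fall. That interferon call was lost without day 0 replicate 2 (adjusted p = 0.114). MYC and nucleolar targets were called lower (median -0.15, 20 of 25 measured members negative, adjusted p = 0.00782; adjusted p = 0.434 with an estimated correlation).

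A further 8 lists were called in the Scr line at adjusted p values from 0.0151 to 0.0430. Cholesterol synthesis (median 0.15), p53 targets (0.13), chaperones of the endoplasmic reticulum (0.13), G1/S and replication (0.12) and glycolysis (0.07) were called higher. Immediate-early genes (-0.18), heat shock chaperones (-0.07) and the TGF-beta response (-0.16) were called lower. With an estimated correlation their adjusted p ran from 0.434 to 0.716. Adjusted over the list alone, the lipid transfer gene STARD4 rose by 0.43 (SE 0.11), PDK1 and ALDOC (0.60, SE 0.16) rose in the glycolysis list, and HSPH1 (-0.75, SE 0.21) and DNAJA1 (-0.46, SE 0.12) fell. In the TGF-beta list TIMP1 (-0.39, SE 0.10) fell and SKIL (0.56, SE 0.15) rose, among immediate-early genes 2 rose and 1 fell, and 0 members passed in the p53, endoplasmic reticulum and replication lists. Each of the 8 calls was lost without 1 or more single arrays of the Scr line: without day 2 replicate 2 the adjusted p was 0.375 for cholesterol synthesis, 0.335 for glycolysis, 0.419 for heat shock, 0.122 for p53 targets, 0.122 for immediate-early genes, 0.625 for the replication list and 0.120 for the TGF-beta list. Without day 0 replicate 1 it was 0.326 for cholesterol synthesis, 0.136 for glycolysis, 0.498 for immediate-early genes and 0.215 for the TGF-beta list, and the replication list turned direction (0.746). Without day 0 replicate 2 it was 0.130 for endoplasmic reticulum chaperones, 0.130 for heat shock, 0.195 for p53 targets and 0.0640 for the TGF-beta list. Without day 2 replicate 1 it was 0.0898 for endoplasmic reticulum chaperones and 0.0670 for the TGF-beta list, and the heat shock call was also lost without either EglN2 shRNA day 2 array (adjusted p = 0.0594 for each).

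Among single genes of the Scr line, the largest moderated t, none past the threshold, belonged to PYGL (0.98), ARHGAP15 (0.90), GPX8 (0.89), CRISPLD1 (0.87) and OLFML3 (0.81) on the positive side. On the negative side they were PPP1R11 (-0.91), CLDN6 (-0.76), the microRNA gene MIR375 (-0.68), NQO1 (-0.63) and SPATA46 (-0.62). CCND1 changed by -0.01 (SE 0.16) and HIF1A by 0.36 (SE 0.13, adjusted p = 0.330), while EGLN1 (-0.02), EGLN3 (-0.09), EPAS1 (-0.20), ESR1 (0.13 and -0.13) and PGR (0.12) did not pass. With the prior variance allowed to follow intensity, limma called 6 probe sets in place of 0, with PPP1R11, OLFML3, GPX8, PYGL and NQO1 among them.

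**Figure D2:**
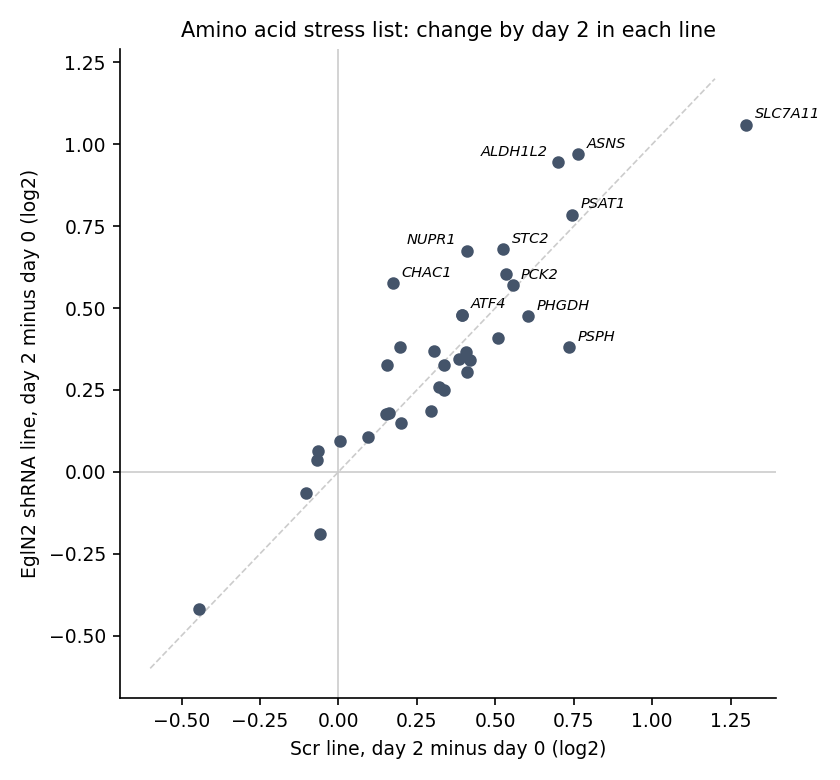
Change by day 2 (log2) of the 35 measured members of the amino acid stress list in the Scr line (horizontal axis) and the EglN2 shRNA line (vertical axis), 1 point per gene, with a dashed line where both are equal. Most points lie in the upper right, with a median of 0.34 on each axis.

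The third comparison asked what doxycycline did in the EglN2 shRNA line beyond what it did in the Scr line, as the difference of the 2 changes. The mitosis list had a median of -0.30 (log2) in this difference, with 34 of 35 measured members negative and 0 past the threshold. Replication-dependent histones (median -0.26, 28 of 28 negative) and the G1/S and replication list (median -0.23, 35 of 38 negative) went the same way. Camera called these 3 lists lower at adjusted p = 3.30e-11, 3.14e-05 and 4.01e-06. With an estimated correlation the calls were lost, at adjusted p = 0.817, adjusted p = 0.969 and adjusted p = 0.969 in the same order. The replication median was -0.12 without Scr day 0 replicate 1, -0.15 without Scr day 2 replicate 2, and -0.14 without EglN2 shRNA day 0 replicate 2 or day 2 replicate 1, and the histone median was -0.16 without Scr day 0 replicate 1 and -0.17 without EglN2 shRNA day 0 replicate 2.

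Named members of the mitosis list were NUSAP1 at -0.52 (SE 0.15), KIF11 at -0.62 (SE 0.19), DLGAP5 at -0.57 (SE 0.18) and CENPE at -0.56 (SE 0.18), and 0 members passed adjusted over the list alone. In the replication list CDT1 read -0.57 (SE 0.18), RRM2 -0.44 (SE 0.16) and CLSPN -0.68 (SE 0.27), and among histones H2BC8 read -0.68 (SE 0.20) and H1-5 -0.54 (SE 0.19), again with 0 past the threshold adjusted over either list alone. Proteasome subunits (median -0.18, 27 of 28 negative, adjusted p = 0.000597; adjusted p = 0.969 with an estimated correlation) were called lower. So were centrosome and cilium genes (median -0.22, 15 of 20 negative, adjusted p = 0.00952, and adjusted p = 0.969 with an estimated correlation). The proteasome and centrosome lists were already higher in the EglN2 shRNA line at day 0 (medians 0.14 and 0.22). Neither was called between the lines at day 2. A difference before doxycycline therefore cannot be told apart from a different response to it. Cyclins and their kinases and inhibitors were called lower at a median of -0.15 over 24 measured members (adjusted p = 0.0444, and adjusted p = 0.817 with an estimated correlation), with CCNB1 at -0.35 (SE 0.14), CCNE1 at -0.41 (SE 0.17) and CDK1 at -0.60 (SE 0.25). CCNB1 and CDK1 are also in the mitosis list and CCNE1 in the replication list, so this call is not separate from those. Proteasome and centrosome calls were lost without the Scr day 0 replicate 1 array (adjusted p = 0.116 for both). The centrosome call was also lost without the EglN2 shRNA day 2 replicate 1 array (adjusted p = 0.874). The cyclin call was lost without day 2 replicate 1 (adjusted p = 0.0867), day 2 replicate 2 (0.110) or day 0 replicate 2 (0.0836) of the EglN2 shRNA line, and without day 0 replicate 2 (0.113) or day 2 replicate 2 (0.107) of the Scr line.

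**Figure D3:**
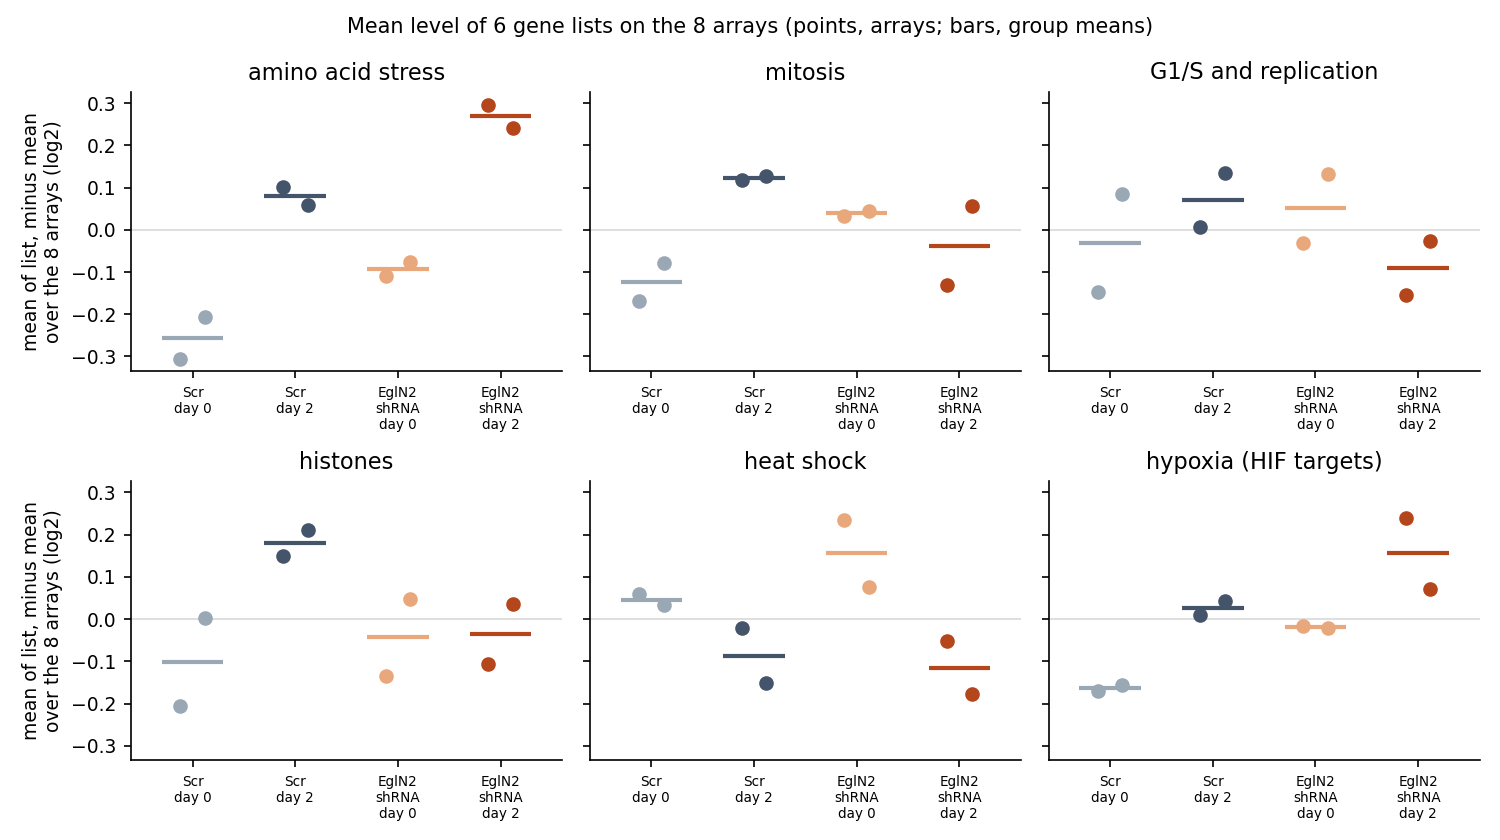
Mean log2 level of 6 gene lists on each of the 8 arrays, relative to the list's mean over all arrays (vertical axis), with 2 points per group for the replicates and a bar at the group mean. The amino acid stress list reads -0.30 and -0.21 in the Scr line at day 0 and 0.10 and 0.06 at day 2, and -0.11 and -0.08 against 0.30 and 0.24 in the EglN2 shRNA line, while the mitosis list reads -0.13 and 0.06 on the arrays of the EglN2 shRNA line at day 2.

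No single gene passed in the difference of changes: limma called 0 probe sets, 1511 (7.12%) had an unadjusted p under 0.05, and the smallest adjusted p was that of ALYREF. ALYREF differed by -1.23 (SE 0.15, confidence interval -1.57 to -0.89, adjusted p = 0.165). With the prior variance allowed to follow intensity, 2 probe sets were called, both of ALYREF. EGLN2 differed by -0.54 (SE 0.15, confidence interval -0.88 to -0.20, adjusted p = 0.671), CCND1 by -0.12 (SE 0.22, confidence interval -0.62 to 0.38) and HIF1A by -0.51 (SE 0.18, adjusted p = 0.676). EGLN1 (0.18), EGLN3 (0.03), EPAS1 (0.22), ESR1 (-0.09 and -0.13) and PGR (-0.14) did not pass. Further values that did not pass were -1.01 for PPM1K, -1.0 for UBXN2A, -0.91 for ARL15 and -0.84 for AGK, and 1.16 for KRTAP9-1, 1.08 for CLDN6, 0.90 for OR7D4, 0.89 for PPP1R11 and 0.78 for CD8B. The amino acid stress list (median 0.02, adjusted p = 0.924), HIF targets (median -0.03, adjusted p = 0.924), FOXO targets (median -0.01, adjusted p = 0.960) and the estrogen response (adjusted p = 0.960) were not called. For the estrogen response the median was 0.01 while the mean was -0.01 and the test pointed down.

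Across the 21214 probe sets the changes of the 2 lines, which share no array, correlated at 0.146 (Pearson) and 0.0897 (Spearman). This is a correlation across genes, which are not independent replicates. An unadjusted p under 0.05 in both lines was seen for 326 probe sets, 263 of them in the same direction, where independent lists would share 157 in either direction. The 2 p-values of a probe set use the same estimate of its spread, so the lists are not independent. The 157 is therefore not the count expected without a shared change. The correlation turned negative, at -0.144, without the EglN2 shRNA day 2 replicate 2 array and was 0.397 without replicate 1 of that group.

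The fourth comparison set the EglN2 shRNA line against the Scr line at day 0, before doxycycline. EGLN2 itself differed by -0.04 (SE 0.11, confidence interval -0.28 to 0.20, adjusted p = 0.889). Without day 0 replicate 1 of the EglN2 shRNA line its sign turned, to 0.05. Amino acid stress genes (median 0.15, 30 of 35 positive), mitosis genes (median 0.15, 33 of 35 positive) and cholesterol synthesis genes (median 0.21, 19 of 19 positive) were called higher in the EglN2 shRNA line. Their adjusted p were 6.18e-05, 6.18e-05 and 8.43e-05, and each had an adjusted p = 0.583 with an estimated correlation. The cholesterol median was 0.11 without Scr day 0 replicate 1, where the centrosome median was 0.14, and 0.31 without Scr day 0 replicate 2. No single gene passed (limma, 0 probe sets, smallest adjusted p = 0.447), and 2213 probe sets (10.4%) had an unadjusted p under 0.05.

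Centrosome and cilium genes (median 0.22, adjusted p = 0.000162; adjusted p = 0.583 with an estimated correlation) were called higher as well, as were HIF targets (median 0.10, adjusted p = 0.00262; adjusted p = 0.583 with an estimated correlation). The proteasome (median 0.14, 28 of 28 positive, adjusted p = 0.000522; adjusted p = 0.612 with an estimated correlation) and glycolysis (median 0.09, adjusted p = 0.0309; adjusted p = 0.612 with an estimated correlation) were called higher, and both calls were lost without Scr day 0 replicate 1 (adjusted p = 0.232 and 0.0967). The glycolysis call was also lost without EglN2 shRNA day 0 replicate 2 (adjusted p = 0.216). In these 7 lists, with those of the paragraph above, 0 members passed adjusted over the list alone. Members with the smallest p included PSPH at 0.47 (SE 0.11) and PSAT1 at 0.51 (SE 0.15), CENPE at 0.40 (SE 0.13), the sterol demethylase CYP51A1 at 0.34 (SE 0.12), P4HA2 at 0.41 (SE 0.10) and PDK1 at 0.48 (SE 0.14).

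Of the single genes at day 0, none past the threshold, those lower in the EglN2 shRNA line with the largest moderated t were BCHE, at -1.57 (SE 0.25), KRTAP9-1 (-0.92), OR7D4 (-0.77), LIN28A (-0.61) and CKAP4 (-0.59). Those higher were SCIN (0.79), CCDC146 (0.73), ST8SIA1 (0.65), AAMDC (0.62) and CACNA2D1 (0.56), all with an adjusted p of 0.447. CCND1 (-0.03), EGLN1 (-0.09), EGLN3 (-0.09), HIF1A (0.13), EPAS1 (0.06), ESR1 (0.01 and -0.12) and PGR (0.01) did not pass.

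The fifth comparison set the lines against each other at day 2, after both had received doxycycline. In the EglN2 shRNA line 13 genes were lower and 1 was higher, on 14 and 2 probe sets (limma). An unadjusted p under 0.05 was seen for 1100 probe sets (5.19%), near the share expected if nothing changed. The largest difference was that of BCHE, the secreted butyrylcholinesterase, at -2.69 (SE 0.25, adjusted p = 0.00973), or 6.48-fold, followed by IGFBP5, a binding protein of insulin-like growth factors, at -1.46 (SE 0.16, adjusted p = 0.0234). ALYREF was lower by 2.47-fold (-1.30, SE 0.11, adjusted p = 0.00424). Both the kinase and the phosphatase of the branched-chain ketoacid dehydrogenase were lower, BCKDK at -1.04 (SE 0.12, adjusted p = 0.0234) and PPM1K at -0.87 (SE 0.11, adjusted p = 0.0328). The 1 gene that was higher was PPP1R11, an inhibitor of protein phosphatase 1, at 0.83 (SE 0.11, adjusted p = 0.0328) on each of 2 probe sets that held the same values.

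Other genes past the threshold were EXOSC7, a subunit of the RNA exosome (-0.97, SE 0.11), the nuclear protein gene GLYR1 (-0.93, SE 0.12), the autophagy gene WDR45B (-0.93, SE 0.13) and the actin regulators CAPZA1 (-0.92, SE 0.12) and PFN2 (-0.87, SE 0.11). The remaining 3, DNAJC10 (-0.83), CKAP4 (-0.78) and AGK (-0.77), were outside the 10 largest falls that the naming rule takes and were named after their values were seen. Of these 13 genes BCHE and CKAP4 had day 0 differences over 50% as large as those at day 2, at -1.57 and -0.59, which did not pass at day 0. PPP1R11 read 9.66 in the EglN2 shRNA line at day 2 and 9.69 at day 0, against 8.83 and 9.74 in the Scr line.

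**Figure D4:**
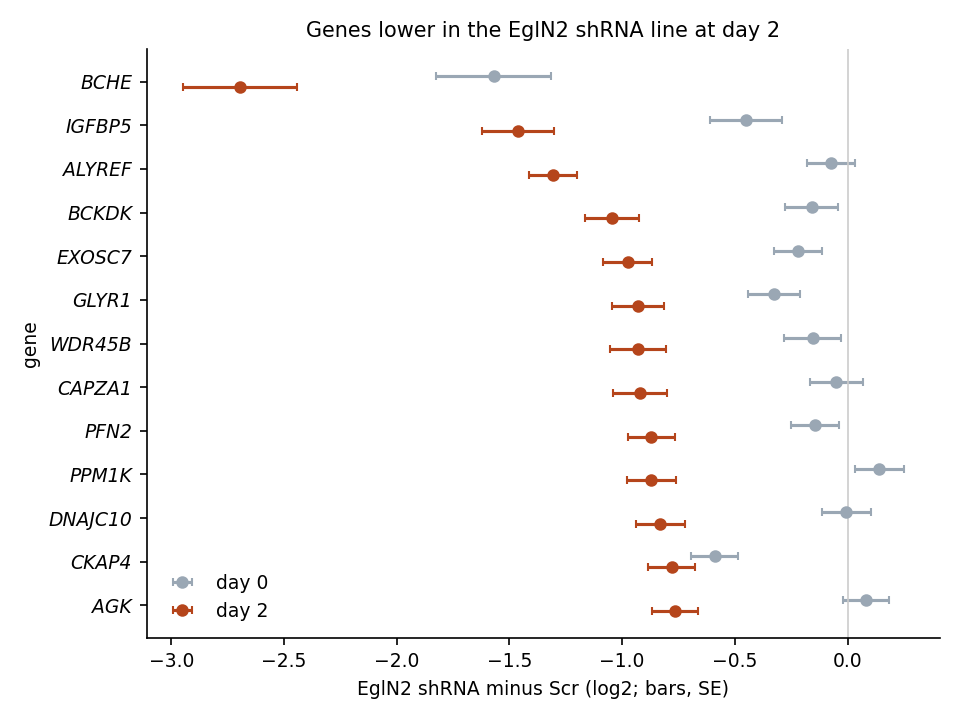
Difference of the EglN2 shRNA line from the Scr line (log2, horizontal axis; bars, SE of the fit) for the 13 genes lower at day 2, with day 2 in orange and day 0 in grey. ALYREF goes from -0.07 at day 0 to -1.30 at day 2, while BCHE is already at -1.57 at day 0.

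By lists, amino acid stress genes were called higher in the EglN2 shRNA line at day 2 (median 0.17, 33 of 35 positive, adjusted p = 3.86e-09; adjusted p = 0.471 with an estimated correlation), with NUPR1 at 0.53 (SE 0.12) and PSAT1 at 0.55 (SE 0.15) short of the threshold over the list alone. Oxidative phosphorylation was called higher by a median of 0.10, with 36 of 39 measured members positive (adjusted p = 9.36e-05; adjusted p = 0.471 with an estimated correlation). Histones were called lower (median -0.22, 27 of 28 negative, adjusted p = 5.12e-08; adjusted p = 0.471 with an estimated correlation). Mitosis genes (median -0.17, 34 of 35 negative, adjusted p = 5.12e-08; adjusted p = 0.471 with an estimated correlation) and the replication list (median -0.14, adjusted p = 1.35e-06; adjusted p = 0.726 with an estimated correlation) were called lower too. In the replication list CDT1, at -0.70 (SE 0.13), was the 1 member lower when adjusted over the list alone. Without EglN2 shRNA day 2 replicate 1 the mitosis call (adjusted p = 0.233) and the replication call (adjusted p = 0.103) were lost and the histone median was -0.13. The replication median was -0.04 without Scr day 2 replicate 2 and -0.21 without Scr day 2 replicate 1, where the oxidative phosphorylation median was 0.07.

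HIF targets (median 0.10, 26 of 34 positive, adjusted p = 0.00201; adjusted p = 0.682 with an estimated correlation), cholesterol synthesis (median 0.13, adjusted p = 0.0116; adjusted p = 0.724 with an estimated correlation) and MYC targets (median 0.06, adjusted p = 0.0342; adjusted p = 0.682 with an estimated correlation) were called higher. In these 3 lists, as in the oxidative phosphorylation, histone and mitosis lists, 0 members passed adjusted over the list alone, and the hypoxia gene NDRG1 read 1.39 (SE 0.39). All 3 were lost without Scr day 2 replicate 1, at adjusted p = 0.0562, 0.865 and 0.202. The HIF call was also lost without EglN2 shRNA day 2 replicate 1 (adjusted p = 0.200), and the cholesterol and MYC calls without replicate 2 of that group (adjusted p = 0.446 and 0.494).

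EGLN2 at day 2 was at 66.9% of the Scr level (-0.58, SE 0.11, confidence interval -0.82 to -0.34, adjusted p = 0.151). CCND1 differed by -0.14 (SE 0.16, confidence interval -0.50 to 0.21, adjusted p = 0.995) and HIF1A by -0.37 (SE 0.13, adjusted p = 0.767), and EGLN1 (0.09), EGLN3 (-0.07), EPAS1 (0.29), ESR1 (-0.09 and -0.25) and PGR (-0.13) did not pass. The count of 16 probe sets fell to 0 without Scr day 2 replicate 1, to 1 without Scr day 2 replicate 2, to 2 without EglN2 shRNA day 2 replicate 1, and to 3 or 4 without any 1 of the 4 day 0 arrays. It was 15 without EglN2 shRNA day 2 replicate 2, with 8 of the 16 among them, and 0 when only the 4 day 2 arrays or all 33297 probe sets were used.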

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

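The tests of a single array, of EGLN2 loss, of day 0 differences and of the shared spread of mitosis genes were chosen only after the results they measure, or closely related values, had been seen. Lists whose change by day 2 differed between the lines, by the test of that difference, were mitosis (adjusted p = 3.30e-11), G1/S and replication (adjusted p = 4.01e-06), histones (adjusted p = 3.14e-05), proteasome (adjusted p = 0.000597), centrosome and cilium (adjusted p = 0.00952) and cyclins (adjusted p = 0.0444). All 6 were lost with an estimated correlation, at adjusted p = 0.817 for mitosis and cyclins and adjusted p = 0.969 for the other 4. The cyclin list had an estimated correlation of -0.0381, below the preset of 0.01, so correlation between its genes does not explain its loss. Groups of 2 arrays are too small for a test of outlying arrays.

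For the mitosis list, the tables argue against 1 array as the source of the difference between the lines: its median in the difference of changes stayed at -0.23 or below whichever array was left out. Mitosis genes also tend to move together from array to array (estimated correlation 0.224), and with that correlation estimated the adjusted p was 0.817. That form also rests on 4 degrees of freedom, so it cannot decide whether their shared spread could give a shift of this size. Part of the difference was present before doxycycline, with a median of 0.15 in favour of the EglN2 shRNA line at day 0 and of -0.17 at day 2, so a difference in growth state between the lines at day 0 cannot be told apart from an effect of the hairpin. The median change was 0.24 in the Scr line and -0.11 in the EglN2 shRNA line, where it rested on day 2 replicate 1 (0 without that array), and an effect of EGLN2 loss on these genes stays open, untested.

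The amino acid stress list was called higher at day 2 in both lines, but with an estimated correlation (0.0740) the adjusted p was 0.110 in the EglN2 shRNA line and 0.302 in the Scr line. That form also rests on 4 degrees of freedom, so the lost calls do not show that the shared spread of its genes gave the shift. Shared spread stays open. The smallest median change in either line with any 1 array left out was 0.30, which argues against a single array. The Scr line, which carries no EglN2 hairpin, showed a median of 0.34, more than 50% of that in the EglN2 shRNA line, which argues against loss of EGLN2 as the cause. Time in culture rather than doxycycline stays open, as 0 arrays come from day 2 without doxycycline. Medium use over 48 h, doxycycline itself and the hairpins used with it cannot be told apart.

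At day 2 falls outnumbered rises between the lines, by 14 probe sets to 2. From day 0 to day 2 all 13 genes called lower fell in the EglN2 shRNA line (median -0.615). In the Scr line 11 of them rose (median 0.17), so the gap at day 2 holds both changes. The 13 genes called lower had a median of -0.15 (log2) at day 0 (interval -0.45 to -0.005) against -0.93 at day 2. This does not decide whether a day 0 difference was the whole source. The genes were picked by their day 2 difference, which enlarges it, and the interval treats genes of the same arrays as independent. As 11 were negative at day 0, a part stays open, as does the whole for BCHE and CKAP4 (median -1.08 at day 0). Scaling between arrays as the whole source is argued against by 16 lower and 2 higher after quantile normalization and 9 lower and 2 higher after centring each array on its median, though RMA values are normalized already and centring took away 5 of the 14 falls. Of the 100 probe sets with the largest moderated t, 75 were negative in the difference of changes, 61 in the EglN2 shRNA line's own change and 19 in that of the Scr line, whose 81 positive ones enter the difference with their sign turned, so the 75 decides nothing. As the labels give neither the number nor the sequence of the EglN2 hairpins, a lowering of other transcripts by the hairpin itself cannot be told apart from an effect of EGLN2 loss.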

How the results depend on the processing

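The averaging over both lines and the comparison of 1 group with the other 3 were tests chosen only after the result was seen. The fit of all probe sets and the correlations for replicate 1 alone and replicate 2 alone were not planned beforehand either. With a replicate block the calls were 13 against 2 in the EglN2 shRNA line, 42 against 0 in the Scr line and 32 against 16 at day 2, and 11 lists against 7 at day 0; the block was not used because same-numbered replicates of the Scr groups correlated at 0.0981, short of the bound of 0.1 set for paired numbers, while the other 5 group pairs ran from 0.163 to 0.271. In the EglN2 shRNA line, 1 value per gene left 1 call, all probe sets 0, only the 4 arrays 0, averaging both lines gave 30, and leaving out 1 array 0 to 2. An intensity trend gave 6 calls in the Scr line (as did adjusted p 0.1, with 6), 2 in the difference of changes and 26 at day 2. At day 2 all probe sets and only the 4 arrays gave 0, adjusted p 0.1 gave 33, the EglN2 shRNA day 2 group against the other 3 gave 46, and leaving out 1 array 0 to 15. An estimated correlation gave 0 lists in every comparison. Leaving out 1 array gave 8 to 15 lists in the Scr line and 7 to 12 at day 0; mitosis in the EglN2 shRNA line ran from 2.21e-06 to 0.424 and replication in the Scr line from 7.54e-05 to 0.746, both turning direction. The correlation of the lines' changes was -0.101 for replicate 1 alone, 0.332 for replicate 2 alone, 0.211 and -0.0335 with the numbers crossed, and ran from -0.144 to 0.397 with 1 array left out. In the EglN2 shRNA line EGLN2 kept its direction with any 1 array left out, from -0.77 to -0.57, though it did not pass in the main fit. The cause was not tested for any of these, except that fewer arrays leave fewer degrees of freedom. Leaving out probe sets marked as hybridizing to several genes could not be run, as no ID carries such a mark, and 1 value per gene gave no EGLN2 value, since its probe set carries 2 names. Signal over background was not measured, and dim genes are limited by it.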

Other observations

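The averaging over both lines and the test of 1 group against the other 3 were tests chosen only after the result was seen. Averaged over both lines (4 arrays against 4), 25 genes were higher at day 2 and 4 were lower on 5 probe sets. The serine synthesis enzymes PSAT1 (0.77, SE 0.10), PSPH (0.56, SE 0.08) and PHGDH (0.54, SE 0.08), the folate enzyme ALDH1L2 (0.82, SE 0.10), the tRNA synthetase gene CARS1 (0.57, SE 0.08), PCK2 (0.56, SE 0.07) and STC2 (0.60, SE 0.09) rose. So did the collagen gene COL12A1 (1.09, SE 0.15), the glycogen phosphorylase PYGL (0.93, SE 0.09), ARHGAP15 (0.85, SE 0.08) and the protease inhibitor SERPINA1 (0.73, SE 0.08). ANXA1 (-0.93, SE 0.14), the estrogen-metabolizing CYP1B1 (-0.87, SE 0.11) and NQO1 (-0.59, SE 0.07) fell, and ALYREF fell by 0.67, made up of -1.29 in the EglN2 shRNA line and -0.06 in the Scr line (adjusted p of the difference 0.165, limma). Among the 35 splits of the 8 arrays into 4 and 4, the split by day called 7 probe sets in a fit with 2 groups, and the highest count of any other split was 1, so 1 split of 35 (2.86%) reached that count, which excludes chance only if the 8 arrays are independent. If replicates are technical, only the splits that keep them together count, which called 7, 1 and 0, too few to exclude it.

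The EglN2 shRNA day 2 group, set against the mean of the other 3 groups, differed in 46 probe sets, 30 lower and 16 higher. All 16 higher ones also rose by day 2 in the Scr line, so a rise by day 2 is not particular to the EglN2 shRNA line. Their levels could still differ between the lines. SLC16A4 was 0.63 above the other 3 groups, with changes of only 0.365 in the EglN2 shRNA line and 0.315 in the Scr line. This leaves a difference between the lines at both days, which did not pass at either. The Scr change was 0.98 for PYGL, against 0.88 in the EglN2 shRNA line. For KDM4D it was 0.26, against 0.58. EGLN2 was among those lower, at -0.65 (SE 0.09, adjusted p = 0.0307), where the 4-group comparisons gave it an adjusted p of 0.134 against day 0 and 0.151 against the Scr line at day 2. EXOSC7 (-0.85), the splicing genes CDC5L (-0.68) and HNRNPM (-0.54), the mitochondrial ribosomal gene MRPS33 (-0.81) and the centromere gene CENPO (-0.77) were lower as well. ALYREF was lower by 1.32 (SE 0.09). Whether the hairpin lowered ALYREF directly was not tested, as the sequence is not in the labels.

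The amino acid stress list was called higher in both lines (medians of 0.34 in each; adjusted p = 0.110 in the EglN2 shRNA line and adjusted p = 0.302 in the Scr line with an estimated correlation). If the shift holds, a response to doxycycline, which can slow mitochondrial translation, to the hairpins used with it, or to time in culture may lie behind it. With 0 arrays from day 2 without doxycycline these readings cannot be told apart. BCKDK and PPM1K, which act in opposite directions on the same enzyme complex, were both lower in the EglN2 shRNA line at day 2, with changes from day 0 of -0.60 and -0.62 in that line and 0.28 and 0.39 in the Scr line. PPP1R11, the 1 gene higher at day 2, changed by -0.02 in the EglN2 shRNA line and read -0.91 in the Scr line (adjusted p = 0.0870).

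The arrays that lay apart most were Scr day 0 replicate 1 and EglN2 shRNA day 2 replicate 2, at -26.6 and 20.1 on the first principal component (35.3% of the variance), and EglN2 shRNA day 2 replicate 1, at -21.9 on the second (17%). Replicates differed most in the EglN2 shRNA line at day 2 (SD of the difference 0.265) and least in the Scr line at day 2 (0.174).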
